A study of Mus musculus with 4 samples.

How the data were processed

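Single-cell RNA was measured in 4 libraries of sorted mouse cochlear cells, 2 at E12.5 and 2 at E14.5, made with the 10x Genomics 3 prime kit of chemistry version 3. Cochleae from a Sox2-GFP line had been separated from the vestibular part, digested and sorted for GFP. The authors deposited 1 matrix per library of raw UMI counts per gene and cell barcode, without normalization. Per the submitters' processing notes, reads were aligned and counted with Cell Ranger 3.0.0 on mm10. The annotation release and the settings for calling cells are not given in the sources used here. Of the gene identifiers, 98.7% were found in GENCODE vM21, which supplied chromosomes and positions; the transgenes Egfp, Creert2, TdTomato and Eyfp are features of the deposited matrices.

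The matrices held 694 and 737 barcodes at E12.5 and 1705 and 3298 at E14.5, with 12945421, 14822617, 39903952 and 74034411 UMIs. Cells with at least 1000 genes and under 10% mitochondrial UMIs were kept; 42, 49, 119 and 221 barcodes had too few genes and 44, 43, 89 and 169 too large a mitochondrial share. Doublets were called per library with scrublet in scanpy 1.11.5 at an expected rate of 6%. It called only 2, 2, 4 and 2 cells, far under that rate, which was a setting and was not measured. Whether the calls were complete is uncertain, and doublets between cell types may remain. As an alternative chosen after the data were seen, cells in the top 5% of doublet scores were removed. The remaining 646, 682, 1565 and 3047 cells had medians of 17976, 19783.5, 19329 and 18356 UMIs and of 4360, 4597.5, 4581 and 4520 genes, and median mitochondrial shares of 3.37%, 3.33%, 4.00% and 4.21%. The 50 most abundant genes took 22.5% to 23.3% of UMIs in each library. Any pair of libraries shared at most 1 barcode.

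Samples, comparisons, tests, gene lists, the rule for named genes and most alternatives were fixed before the data were examined; those chosen later are named as such. Each age was clustered on its own with both libraries together: counts scaled to 10000 per cell and log-transformed, 2000 variable genes without cell cycle, ribosomal, mitochondrial, hemoglobin, Xist and Y-linked genes, 30 principal components, 15 neighbours and Leiden resolution 1 (igraph 0.11.9). Clusters were named by hand from 15 marker lists: prosensory, hair cell, medial, lateral, roof, otic epithelium, vestibular epithelium, glia, neuron, mesenchyme, chondrocyte, endothelium, macrophage, erythroid and melanocyte. The ending "-like" marks such a name, which rests on transcripts alone. Prosensory, hair cell, medial, lateral, roof and otic epithelium clusters made up the cochlear epithelium.

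Counts of UMIs were summed per library over the cells of a class, since cells of a library are not replicates. The sums of the epithelium held 150, 174, 184 and 614 cells and 3266558 to 16170992 UMIs, those of lateral-like cells 847649 to 3584847 UMIs, those of roof-like cells 31, 36, 32 and 141 cells and 856784 to 4716083 UMIs, and those of the Fgf20 clusters 334564 to 1955667 UMIs. Levels are CPM, the counts of a gene per 1000000 UMIs of the sum. Ages were compared with edgeR 4.0.16 in R 4.3.3 (TMM scaling, filterByExpr, glmQLFit and the quasi-likelihood F test), with Benjamini-Hochberg adjustment and a threshold of 0.05. Comparisons were planned for a class with at least 30 cells in each library. Prosensory-like and medial-like cells did not reach this at E12.5, so their age comparisons and the interaction between them were not run, and the pair of clusters led by Fgf20, with fewer than 30 cells in each E12.5 library, was compared instead as a choice made after the data were seen. Standard errors are those of the fitted log2 change.

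For the axis from apex to base, fewer than 60 prosensory-like cells in a library meant, by the planned rule, that all epithelial cells except roof-like cells were scored (119, 138, 152 and 473 cells) by the mean within-library z of Fst, Msx1, Hmga2 and Lin28b minus that of Inhba and A2m. Per library, 39, 46, 50 and 157 cells in each of the upper and lower ranges were summed, with 41, 46, 52 and 159 between them, and compared in edgeR with the library as a term and without the 6 score genes. The change of this difference with age was tested as an interaction. The ranges are ranges of a score and not positions.

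Named genes were, per comparison of ages, the 10 largest increases and the 10 largest decreases among genes with adjusted p under 0.05, an average log2 CPM of at least 5 and no overlap between ages. Numbered gene models, ribosomal genes, hemoglobins, Xist and Y-linked genes were counted but not ranked. For the score ranges the same number was taken with the same direction in all 4 libraries, for the interaction up to 5 per direction, and for each list up to 4 members with the smallest p, of which the text gives a part. Some genes are not reported here. Sox2, Cdkn1b, Atoh1, Fgf20, Fgf10, Bmp4, Jag1, Fst, Msx1, Hmga2, Lin28b, Inhba, A2m, Ptch1, Gli1 and Hhip were followed throughout. Of 35 lists fixed, 28 were counted in the epithelium and 22 with at least 3 measured members were tested with camera in limma 3.58.1 on voom values, with a preset correlation of 0.01 and with an estimated one, and with fry. Besides the marker lists they covered apical and basal genes, the Hedgehog, Notch, BMP and activin, Wnt, FGF and retinoic acid pathways, Hedgehog targets, heterochronic, S phase, G2 and M phase, cell cycle inhibitor, hair cell, supporting cell and prosensory, tectorial, ion transport and otic transcription factor genes, and dissociation response and mitochondrially encoded genes. Counts of the S phase, G2 and M phase and mitochondrially encoded lists in lateral-like and roof-like cells and the Fgf20 clusters were made after the data were seen. The lists were written from general knowledge of the tissue and not from these libraries.

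Shares of cells carry exact Clopper-Pearson 95% intervals and were compared by exact two-sided permutation over the 6 ways to pick 2 of 4 libraries. Cells were counted as cycling with at least 1 UMI of Mki67 or Top2a after random thinning to 5000 UMIs; 9, 8, 5 and 2 epithelial cells under that depth were left out. Intervals and the floor of 3 counts cover counting error only, and free RNA in droplets can give UMIs of genes a cell does not express. The alternatives were DESeq2 1.42.0, RLE scaling, no filter on low counts, each library left out, the replicate number as a term, doublet calls kept, a mitochondrial limit of 5%, Leiden resolution 0.6, equal cell numbers, score ranges of another size and another score. Added after the data were seen were cells with an Egfp UMI only, the 5% limit for the share of cycling cells, the otic and vestibular-like clusters re-clustered alone with 1000 genes and 15 components, and score ranges taken within each cluster. Deviations of replicates with the same number were not correlated between ages (correlations across genes of -0.0564 to 0.0475, where genes are not independent), so the numbers name samples and do not pair them. Replicates differed by more than counting error, with a chi-square per degree of freedom of 1.48 in the E12.5 epithelium and 5.33 in the E14.5 epithelium.

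The tests were checked on simulated data with the measured depths and spread, in which up to 200 genes were changed. A 2-fold change was recovered for 94% of them in the epithelium, 97% in all cells, 50% in lateral-like, 66.3% in roof-like cells, 39.8% in the Fgf20 clusters, 55.7% between score ranges and 22% in the interaction, and a 4-fold change for 87% to 100%. The changed genes were drawn only from genes above a minimum mean level, so these rates do not cover lower genes that were also tested. For the score ranges and the interaction the spread was estimated without the library as a term. Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1, scikit-learn 1.9.0 and matplotlib 3.10.9 were used.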

Results

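The series asks how cells of the mouse cochlear duct differ between the embryonic days E12.5 and E14.5 and along the axis from apex to base. Cells with a Sox2-GFP reporter, which marks cells that transcribe the otic and neural progenitor gene Sox2, had been sorted from dissected cochleae. After filtering, 646 and 682 cells remained in the E12.5 libraries (replicates 1 and 2) and 1565 and 3047 in the E14.5 libraries. The labels do not name the animals behind a library, so every p-value measures the spread between these samples. Xist, the RNA that coats the inactive X chromosome, had a UMI in 98.6% and 98.1% of E12.5 cells and in 0.319% and 0.394% of E14.5 cells. A UMI of Ddx3y, Eif2s3y, Kdm5d or Uty, which lie on the Y chromosome, was found in 0.619% and 0.733% of E12.5 cells and in 93.0% and 92.9% of E14.5 cells. Age and sex therefore coincide in every comparison of ages.

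Clusters named from marker lists as cochlear epithelium held 24.4% ± 1.62 of cells at E12.5 and 16% ± 5.94 at E14.5 (mean ± SD of 2 libraries per age). The libraries stood at 23.2%, 25.5%, 11.8% and 20.2% (exact 95% intervals 20 to 26.7, 22.3 to 29, 10.2 to 13.5 and 18.7 to 21.6). The difference of -8.41 points had a two-sided exact permutation p of 0.333, the smallest that 2 against 2 libraries allow. Vestibular-like epithelium made up 12.5% ± 2.82 and 2.93% ± 1.98, and glia-like cells made up 6.91% ± 0.800 and 13.4% ± 0.638. Neuron-like cells were 36.8% ± 7.27 and 31.0% ± 4.04 (exact permutation p = 0.667), and mesenchyme-like cells 8.40% ± 2.02 and 8.67% ± 8.88 (exact permutation p = 1). Macrophage-like and endothelium-like clusters appeared at E14.5 with 2.12% ± 0.0742 and 0.775% ± 0.168 of cells. No cluster was named so at E12.5, where 0 of 646 and 0 of 682 cells lay in such a cluster (exact upper limits 0.569% and 0.539%), which leaves single cells in other clusters uncounted. No cluster was named as hair cells, chondrocytes, erythroid cells or melanocytes. Clusters that no marker list named were 11% ± 0.00449 and 25.1% ± 5.88. Within the epithelium, lateral-like cells were 7.07% ± 0.368 and 3.84% ± 0.554 of all cells and roof-like cells 5.04% ± 0.339 and 3.34% ± 1.83. At E14.5, prosensory-like cells were 3.19% ± 0.00808 and medial-like cells 5.59% ± 3.56, with 3.07% in replicate 1 and 8.11% in replicate 2. Each of these shares rests on the sort, the dissection and the genes that define the classes. The E14.5 cells counted include clusters led by genes of tissues other than the ear. Among neuron-like cells, 306 lay in a cluster led by genes of olfactory neurons and 194 in one led by genes of cortical neurons. Among unnamed cells, 225 lay in a cluster led by pituitary genes. Shares of all cells therefore do not describe the cochlea alone. Among cells with an Egfp UMI alone, the epithelial difference was +3.04 points, and with a lower clustering resolution it was -16.6 points. The vestibular-like shares were then 7.65% and 6.27% (exact permutation p = 1), and each E12.5 lateral-like cell lay in a cluster named otic epithelium. The glia-like difference was +20.1 points among cells with an Egfp UMI, against +6.50. Under a limit of 5% mitochondrial UMIs the E14.5 shares were 1.33% ± 0.860 for prosensory-like and 1.64% ± 1.30 for lateral-like cells. That limit kept 9 of 50 and 44 of 97 prosensory-like and 9 of 54 and 58 of 129 lateral-like cells at E14.5, and 38 of 44 and 40 of 50 lateral-like cells at E12.5.

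In the cochlear epithelium, 11 of 13 genes of the cochlear matrix and the tectorial membrane, the sheet above the hair cells, were higher at E14.5, and the Notch effector Hes1 and 35 of 40 S phase genes were lower. As lists, both passed a set test with a preset correlation and neither passed with an estimated one (adjusted p = 0.406 for each). With 2 libraries per age the version with an estimated correlation could hardly pass and does not decide. Tecta, which encodes alpha-tectorin, rose from 24.7 ± 0.229 to 243 ± 14.1 CPM (mean ± SD, n = 2 libraries per age), a log2 change of +3.24 (standard error (SE) 0.10, adjusted p = 9.20e-09). The gene lies on chromosome 9 at 42329619 to 42399929. Mia, which encodes a secreted matrix protein of cartilage, rose from 83.1 ± 9.35 to 727 ± 179 CPM (log2 +3.08, SE 0.15). Hes1, on chromosome 16 at 30064384 to 30067796, fell from 840 ± 35.7 to 105 ± 8.16 CPM (log2 -3.05, SE 0.08, adjusted p = 1.16e-09). Wnt5a, a ligand of planar polarity signalling, rose from 20.3 ± 0.359 to 78.0 ± 8.73 CPM (log2 +1.90, SE 0.13, adjusted p = 4.98e-06).

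Across the 11624 genes tested in the epithelium with edgeR's quasi-likelihood F test and Benjamini-Hochberg adjustment, 1458 were higher and 1834 lower at E14.5. Of the 3292 called genes, 3291 had both E14.5 libraries on 1 side of both E12.5 libraries, a pattern that 67.1% of tested genes showed and that chance gives to 33.3%. The other genes with the largest increases were the small heat shock gene Cryab (log2 +3.19, SE 0.35), Tectb (+3.11, SE 0.24), which encodes beta-tectorin, Tmem132c (+2.87, SE 0.21) and the actin-severing gene Gsn (+2.84, SE 0.26). Next came the hormone gene Pthlh (+2.53, SE 0.63), the collagen processing gene Pcolce2 (+1.96, SE 0.26) and the glycolytic gene Aldoc (+1.84, SE 0.15). Pthlh was -0.22 when the otic and vestibular-like cells were re-clustered and those then named vestibular-like were left out. The other large decreases were Hist1h2ap (-3.38, SE 0.07), Ccdc85b (-2.51, SE 0.17), the mitochondrial leucyl-tRNA synthetase gene Lars2 (-2.50, SE 0.22), Hist1h2ae (-2.40, SE 0.10) and the stress response gene Gadd45g (-1.83, SE 0.11). Pgk1 (-1.97, SE 0.15), Gstp1 (-1.90, SE 0.12) and Hist1h4d (-1.78, SE 0.13) also fell. These and the other histone genes belong to families of near-identical copies, so the assignment of their reads is uncertain. Lars2 and Ccdc85b also fell in lateral-like cells and in the Fgf20 clusters. Each library held cells of 1 age, so a difference in preparation between libraries cannot be told apart from age. Tecta, Tectb, Mia and Epyc were also leading genes of the E14.5 medial-like cluster, and Hist1h2ap, Hist1h2ae and Lars2 of an E12.5 epithelial cluster, so their changes and the naming of cells share genes.

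**Figure D1:**
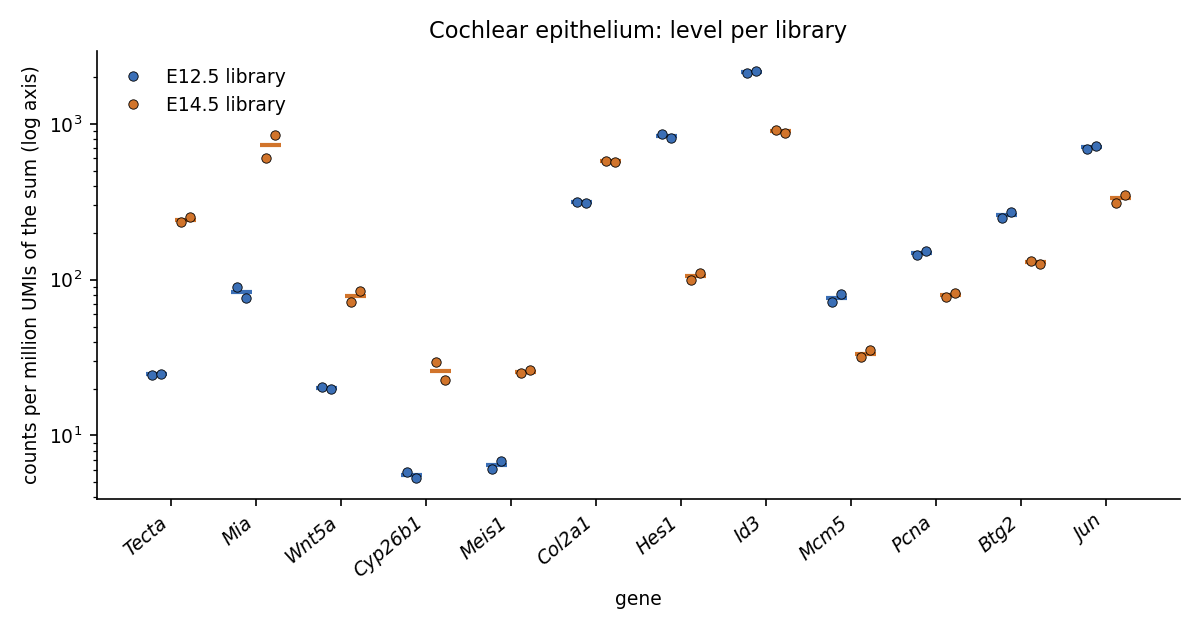
Level of 12 genes in the cochlear epithelium, in CPM summed over its cells on a log axis, with 1 point per library and a bar at the mean of each age (blue, E12.5; orange, E14.5; n = 2). Tecta stood at 24.7 and 243 CPM and Hes1 at 840 and 105 CPM, with no overlap between ages.

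Among developmental genes fixed for reporting, Fgf20, a ligand needed for the sensory domain, rose by a log2 of +0.72 (SE 0.22), Fgf10, a ligand of the medial duct, by +0.95 (SE 0.16) and Bmp4, a ligand of the lateral duct, by +0.68 (SE 0.09). The Notch ligand gene Jag1 fell (-0.44, SE 0.09), as did the apical genes Msx1 (-1.05, SE 0.34) and Lin28b (-0.85, SE 0.28). Sox2 stood at 111 ± 11.6 and 132 ± 27.4 CPM (log2 +0.16, SE 0.14, adjusted p = 0.403). The cell cycle inhibitor gene Cdkn1b (-0.03, SE 0.12), the apical genes Fst (-0.67, SE 0.39) and Hmga2 (+0.25, SE 0.23), the basal gene Inhba (-0.00, SE 0.38) and the Hedgehog targets Ptch1 (-0.23, SE 0.17) and Gli1 (+0.07, SE 0.31) did not pass. Atoh1, A2m and Hhip were too low to be tested.

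Of the gene lists fixed beforehand, the tectorial, ion transport, Wnt and mitochondrially encoded lists passed upward and the S phase and the G2 and M phase lists downward in a test with a preset correlation. None passed with an estimated one (smallest adjusted p = 0.406), a version for which the libraries were too few to decide. Of 13 measured genes of the tectorial membrane and cochlear matrix, 11 rose and the other 2 did not pass (11 adjusted over the list alone), among them Epyc (log2 +6.30, SE 0.49) and Col2a1, a fibrillar collagen gene that went from 313 ± 2.70 to 574 ± 3.27 CPM (+0.81, SE 0.06). Leaving out the 6 members that also served to name clusters, 6 of 7 rose. Of 7 genes of ion transport and gap junctions 4 rose (5 adjusted over the list alone), with the gap junction gene Gjb2 going from 117 ± 2.90 to 284 ± 42.4 CPM (+1.22, SE 0.10) and the cotransporter gene Slc12a2 at +0.88 (SE 0.14). Of 22 Wnt pathway genes 10 rose (10 adjusted over the list alone), including the ligand genes Wnt5a and Wnt7a (+2.02, SE 0.25), the secreted modulator gene Sfrp2 (+0.71, SE 0.12) and the receptor gene Fzd2 (+0.53, SE 0.10). Of 40 S phase genes 35 fell (36 adjusted over the list alone), with a median log2 of -0.80; the replication factor genes Mcm5 (-1.24, SE 0.11), Pcna (-0.96, SE 0.09) and Nasp (-0.91, SE 0.08) and the helicase gene Hells (-1.30, SE 0.10) were examples. Of 52 G2 and M phase genes 12 fell and 1 rose (12 and 1 adjusted over the list alone), including the spindle genes Ndc80 (-1.14, SE 0.25) and Cdc20 (-0.56, SE 0.10); the median of the list was -0.26, and 0.00288 when the otic cells were re-clustered. Of 13 mitochondrially encoded genes 9 rose and 2 fell (9 and 3 adjusted over the list alone), with mt-Co3 at +0.65 (SE 0.06) and mt-Atp8 at -1.74 (SE 0.09). The reading frame of mt-Atp8 overlaps that of mt-Atp6 (+0.61, SE 0.05), so the split of reads between them is uncertain.

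These 6 of the 22 lists tested passed limma's camera with a preset correlation of 0.01. Adjusted p-values were 4.29e-08 for the tectorial list, 0.00407 for ion transport, 6.16e-04 for Wnt, 8.71e-19 for S phase, 0.00648 for G2 and M phase and 0.00739 for mitochondrially encoded genes. With an estimated correlation none passed: adjusted p = 0.406 for the tectorial, ion transport, Wnt and S phase lists, adjusted p = 0.716 for G2 and M phase and adjusted p = 0.591 for mitochondrial genes. That version had only 2 residual degrees of freedom here and could hardly have passed. Its result does not decide for or against a list. In fry, which tests whether a set moves 1 way without comparing it with other genes, the adjusted p was 0.0231 for the tectorial list, 0.0231 for ion transport, 0.0318 for Wnt and 0.0257 for S phase, and 0.413 and 0.389 for the other 2.

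**Figure D2:**
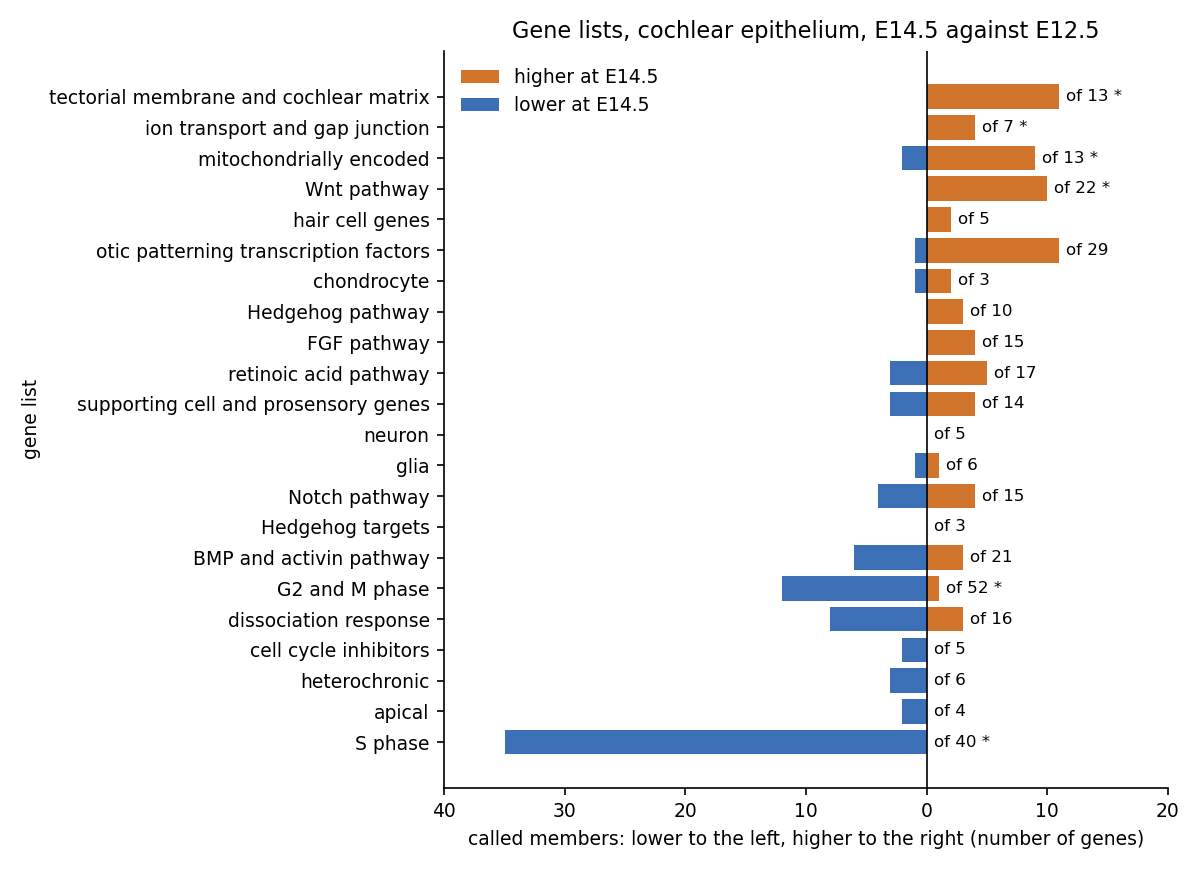
Number of called members per gene list in the cochlear epithelium (adjusted p under 0.05), with genes higher at E14.5 drawn to the right in orange and genes lower at E14.5 to the left in blue; the text beside each bar gives the number tested and a star marks an adjusted camera p under 0.05 with the preset correlation. The S phase list reaches 35 of 40 to the left and the tectorial list 11 of 13 to the right.

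Signalling lists whose test did not pass differed in direction. Over all genes, called Notch, BMP and activin and retinoic acid members went both ways, and called FGF and Hedgehog pathway members rose. In the Notch list 4 of 15 rose and 4 fell (4 and 5 adjusted over the list alone; camera adjusted p = 0.388): the receptor genes Notch1 (log2 +0.59, SE 0.11) and Notch2 (+0.72, SE 0.15) rose, and Hes1 and Jag1 fell. In the BMP and activin list 3 of 21 rose and 6 fell (3 and 7 adjusted over the list alone; adjusted p = 0.198), with the BMP targets Id3 going from 2156 ± 39.0 to 900 ± 29.2 CPM (-1.32, SE 0.05), Id1 at -0.97 (SE 0.06), Id4 at -1.14 (SE 0.13) and the inhibitory Smad7 at -0.82 (SE 0.09). In the retinoic acid list 5 of 17 rose and 3 fell (7 and 4 adjusted over the list alone; adjusted p = 0.180): the degrading enzyme gene Cyp26b1 went from 5.57 ± 0.353 to 26.1 ± 4.97 CPM (+2.13, SE 0.23), the synthesising enzyme gene Aldh1a1 changed by +2.72 (SE 0.48), the receptor gene Rarg by +1.24 (SE 0.27) and the binding protein gene Crabp2 by -0.61 (SE 0.07). Of 15 FGF genes 4 rose (5 and 1 lower adjusted over the list alone; adjusted p = 0.302), including Fgfr2 (+0.48, SE 0.13) and Spry2 (+0.40, SE 0.12). Of 10 Hedgehog pathway genes 3 rose (3 adjusted over the list alone; adjusted p = 0.198), the coreceptor genes Boc (+1.63, SE 0.21) and Cdon (+1.56, SE 0.26) and the transducer gene Smo (+0.56, SE 0.11). Without cluster-naming markers the counts were 3 up and 2 down of 10 Notch genes, 1 and 3 of 16 BMP genes, 4 and 3 of 16 retinoic acid genes and 2 up of 12 FGF genes.

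Among lists of cell states, 11 of 29 otic transcription factors rose and 1 fell (11 and 1 adjusted over the list alone; camera adjusted p = 0.0541), with Meis1 going from 6.48 ± 0.505 to 25.7 ± 0.769 CPM (log2 +1.92, SE 0.19), Nr2f1 at +0.53 (SE 0.09) and Irx5 at +0.44 (SE 0.08). Of 14 supporting cell and prosensory genes 4 rose and 3 fell (4 and 3 adjusted over the list alone; adjusted p = 0.649), with the Notch effector genes Hey2 at +0.89 (SE 0.25) and Hey1 at -0.67 (SE 0.15) and Prdm16 at +0.92 (SE 0.18). Of 5 hair cell genes 2 rose, Insm1 (+2.13, SE 0.52) and Cib2 (+0.99, SE 0.23), with 3 higher and 1 lower adjusted over the list alone (adjusted p = 0.372). Of 6 heterochronic genes 3 fell (4 adjusted over the list alone; adjusted p = 0.160): Lin28b, Trim71 (-1.0, SE 0.28) and Igf2bp1 (-0.31, SE 0.09). Of 5 cell cycle inhibitor genes 2 fell, Btg2 from 262 ± 17.1 to 130 ± 4.37 CPM (-1.08, SE 0.08) and Cdkn1a (-1.06, SE 0.11), with 1 higher and 2 lower adjusted over the list alone (camera adjusted p = 0.302, fry adjusted p = 0.0257). Btg2 is also a member of the dissociation response list. Of the 4 apical genes 2 fell (2 adjusted over the list alone; adjusted p = 0.160), and Inhba was the 1 basal gene measured.

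Lists of the response to dissociation and of other cell types did not pass as lists where they were tested. In the dissociation response list 3 of 16 rose and 8 fell (4 and 9 adjusted over the list alone; camera adjusted p = 0.0694), with the immediate early gene Jun going from 708 ± 26.6 to 332 ± 27.7 CPM (log2 -1.15, SE 0.07), the chaperone gene Hspa8 at -0.58 (SE 0.06) and Hspa1a at -4.30 (SE 0.45). Of 6 glia markers Fabp7 rose (+2.19, SE 0.60) and Ednrb fell (-1.40, SE 0.35), the same counts as adjusted over the list alone (adjusted p = 0.649). The 5 neuron markers did not pass, with Stmn2 at +1.49 (SE 0.65, adjusted p = 0.113) and a list p of 0.302 after adjustment. Of 3 chondrocyte markers Matn4 (+1.85, SE 0.47) and Col9a1 (+0.49, SE 0.09) rose and Matn1 fell (-1.71, SE 0.42; list adjusted p = 0.388; 2 and 1 adjusted over the list alone). The single mesenchyme marker tested, Prrx2, rose (+1.24, SE 0.36), as did the single erythroid marker, Hbb-bs (+3.62, SE 0.68, at 5.18 CPM at E14.5). The melanocyte markers Mitf (+0.94) and Kit (+0.21) did not pass, and no endothelium or macrophage marker was high enough to test. The reporter transcript Egfp fell from 380 ± 23 to 223 ± 57.3 CPM (-0.85, SE 0.14).

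The epithelial counts depended on the E12.5 libraries: 578 higher and 871 lower without replicate 1, and 374 and 648 without replicate 2. With DESeq2 they were 556 and 1010, in cells with an Egfp UMI 974 and 1221, and at a lower clustering resolution, where the E12.5 epithelium took in a vestibular-like cluster and the E14.5 epithelium lost its roof-like cells, Meis1 (-0.77), Notch2 (-0.07), Fgfr2 (-0.60) and Cib2 (-0.03) lay on the other side of 0.

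In the clusters named lateral-like from markers of the outer sulcus, 40 of 48 G2 and M phase genes were higher at E14.5 and 0 lower (43 and 0 adjusted over the list alone; 41 of 49 with the otic cells re-clustered). Of 33 S phase genes 2 were higher and 2 lower. No set test was run in this class. Of 13 mitochondrially encoded genes 9 were higher and 2 lower here, and most E14.5 cells of the class had over 5% mitochondrial UMIs. Each age was clustered on its own. At E12.5 cycling cells gathered in an epithelial cluster outside this class (69 of 105 cells there against 1 of 91 here). The share of cycling cells in the whole epithelium was 27.8% and 27.9% at the 2 ages (28.9% and 37.7% under 5% mitochondrial UMIs). The change is therefore one of the class as clustered and is not shown for lateral cells as a whole. Ube2c, which encodes an enzyme of the anaphase-promoting complex, rose from 8.67 ± 5.58 to 421 ± 163 CPM (n = 2 libraries per age, log2 +5.58, SE 0.34, adjusted p = 2.67e-08), and the topoisomerase gene Top2a from 3.35 ± 0.273 to 130 ± 16.9 CPM (+5.28, SE 0.31, adjusted p = 2.61e-08). Nusap1 (+5.13, SE 0.38), Ccnb1 (+5.0, SE 0.54), Spc25 (+4.92, SE 0.49), Mki67 (+4.21, SE 0.46) and Ccna2 (+4.16, SE 0.54), all genes of G2 and mitosis, rose with them. Hes1 fell from 1019 ± 139 to 88.3 ± 29.4 CPM (-3.60, SE 0.17), and the antiproliferative gene Btg2 from 469 ± 78.9 to 99.4 ± 4.10 CPM (-2.24, SE 0.14). Btg2 also belongs to the dissociation response list, of which Jun and Atf3 fell here too. The LIM homeodomain gene Isl1, a marker of the sensory domain, fell from 1014 ± 34.7 to 608 ± 157 CPM (-0.75, SE 0.13).

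The other largest increases were the matrix gene Fbln2 (log2 +5.23, SE 0.80), the otoconial gene Oc90 (+4.58, SE 0.24) and Lmo3 (+4.34, SE 0.74). Lmo3, Bmp4 (+1.83, SE 0.16), Gata2 and Id3 were also among the markers used to name the cluster. Oc90, a roof marker, was -0.71 when the otic cells were re-clustered. The other largest decreases were Ccdc85b (-3.33, SE 0.28), the phosphatase gene Dusp5 (-2.54, SE 0.27), Lars2 (-2.41, SE 0.26), the lamin gene Lmna (-2.30, SE 0.24), Rrm2b (-2.29, SE 0.39), Tnfrsf12a (-2.21, SE 0.18), Ncoa7 (-2.12, SE 0.19) and Klf6 (-2.11, SE 0.17). Jag1 fell from 351 ± 2.06 to 116 ± 5.61 CPM (-1.60, SE 0.13), and Sox2 (-0.88, SE 0.25), Fgf10 (-2.10, SE 0.44), Hey1 (-1.22, SE 0.22), Lin28b (-1.36, SE 0.29) and Id3 (-0.92, SE 0.08) fell too. At the lower clustering resolution each E12.5 lateral-like cell lay in a cluster named otic epithelium. Whether the falls of these genes and of Isl1 lie within the same kind of cell was not tested. Gjb2 (+1.08, SE 0.18), Col9a3 (+1.36, SE 0.14), Fgfr2 (+1.19, SE 0.26) and Gata2 (+1.44, SE 0.27) rose. Cdkn1b (-0.51, SE 0.16), Fst (-0.68, SE 0.26) and Hmga2 (-0.10, SE 0.18) did not pass. The dissociation response genes Jun (-1.04, SE 0.12) and Atf3 (-3.64, SE 0.52) fell.

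Of 8689 genes tested with edgeR and Benjamini-Hochberg adjustment in lateral-like cells, 433 were higher and 481 lower. The counts were 220 and 259 without E12.5 replicate 1, 188 and 193 without E12.5 replicate 2, 739 and 726 without E14.5 replicate 1, 144 and 183 with DESeq2, and 652 and 589 with no filter on low counts. The sums held 44, 50, 54 and 129 cells, and a simulated 2-fold change was recovered at this size for 50% of genes drawn above a minimum level.

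Cycling cells were also counted. After each cell was thinned to 5000 UMIs, a UMI of Mki67 or Top2a, genes of dividing cells, was found in 0 of 42 and 1 of 49 lateral-like cells at E12.5 and in 11 of 50 and 35 of 128 at E14.5. The means were 1.02% ± 1.44 and 24.7% ± 3.78 (two-sided exact permutation p = 0.333, the smallest possible). In roof-like cells the shares were 12.9% and 20% at E12.5 and 35.5% and 31.9% at E14.5. In the clusters led by Fgf20 they were 14.3% and 4.17% at E12.5 and 4.0% and 2.06% at E14.5. In the whole epithelium they were 27.8% ± 2.75 and 27.9% ± 3.95 (exact permutation p = 1). Among cells under 5% mitochondrial UMIs the differences between ages were +8.82 points in the epithelium, +22.5 in lateral-like cells and +0.39 in the Fgf20 clusters, against +0.0839, +23.7 and -6.20 over all cells. The lateral-like value then rests on 8 and 57 cells at E14.5. Without thinning the difference in the Fgf20 clusters was -14.7 points. For comparison, neuron clusters with Gata3 and Isl1 gave 0.962% (1 of 104 cells) and 0 of 88 at E12.5 and 11.6% and 6.31% at E14.5. Their median depths were 17872.5 to 29924 UMIs, against 12710 to 27941 in the otic clusters. Whether cells of these neuron clusters divide was not tested, so their shares can hold dividing cells as well as background. The neuron shares were higher at E14.5, and the Fgf20 cluster of E14.5 lay below them. At E12.5 the epithelial cluster rich in histone genes, outside the lateral-like class, held 69 cycling cells (65.7%), against 42 and 43 in the whole epithelium of the 2 libraries. With the otic cells re-clustered, the log2 change of Mki67 in lateral-like cells was +4.53.

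The clusters named roof-like, after the part of the duct opposite the sensory epithelium, were not alike in lead genes at the 2 ages. In them the activin antagonist gene Fst fell from 99.8 ± 57.0 to 2.55 ± 1.5 CPM (n = 2 libraries per age, log2 -5.75, SE 0.55, adjusted p = 0.00125). The orphan nuclear receptor gene Rorb fell from 104 ± 6.84 to 10.9 ± 2.48 CPM (-3.45, SE 0.22). The aminopeptidase gene Enpep rose from 1.59 ± 0.60 to 48.7 ± 1.35 CPM (+4.77, SE 0.39, adjusted p = 8.88e-04), and the transcription factor genes Nfix and Meis1 rose from 7.53 ± 0.751 to 73.2 ± 14.3 CPM (+3.22, SE 0.29) and from 14.6 ± 0.749 to 83.3 ± 2.08 CPM (+2.42, SE 0.21). The protocadherin gene Pcdh20 (+3.46, SE 0.32), Sbspon (+3.09, SE 0.55), Cryab (+2.95, SE 0.38), the claudin gene Cldn8 (+2.77, SE 0.52), the fibronectin gene Fn1 (+2.37, SE 0.58) and Rmst (+2.32, SE 0.48) rose as well. The proteoglycan genes Dcn (-3.01, SE 0.23) and Lum (-2.34, SE 0.20) fell, with Clu (-2.26, SE 0.19), Dlk1 (-2.25, SE 0.30), the carbonic anhydrase gene Car14 (-2.22, SE 0.42), Bmp4 (-1.49, SE 0.20), Jag1 (-0.94, SE 0.14), Hmga2 (-0.90, SE 0.17) and Cdkn1b (-0.86, SE 0.21). Pgk1 (-2.40) and Hist1h2ap (-2.27), from families of like copies, fell here too. The retinoic acid enzyme gene Aldh1a3 stood at +3.63 (SE 0.63), and at -1.13 when the otic cells were re-clustered. Sox2 did not pass (+1.70, SE 0.48, adjusted p = 0.0629).

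Of 8990 genes tested with edgeR and Benjamini-Hochberg adjustment in roof-like cells, 308 were higher and 465 lower. Without E12.5 replicate 1 these were 4 and 13, without E12.5 replicate 2 they were 6 and 22, without E14.5 replicate 1 they were 879 and 953, without E14.5 replicate 2 they were 484 and 659, and with DESeq2 86 and 175. With no filter they were 812 and 848, in cells with an Egfp UMI 187 and 286, and after re-clustering 729 and 909. The class was not stable at E14.5. Its E14.5 cluster was led by Oc90, Hmx2 and Pthlh, and its E12.5 cluster by Otx2, Wnt4 and Gsc. Hmx2 is on the vestibular marker list, and Oc90 and Pthlh were also lead genes of an E12.5 vestibular-like cluster. Oc90 and Ecel1 were lead genes of the class at both ages. The changes are therefore those of the clusters as named and are not shown for the roof of the duct. When the otic cells were re-clustered, 30 of 31 and 35 of 36 roof-like cells stayed in the class at E12.5 but 25 of 32 and 32 of 141 at E14.5. Of replicate 2 at E14.5, 107 cells joined vestibular-like cells. At the lower resolution each of the E14.5 cells did. Of the 24 genes named and called, 20 passed in the same direction after re-clustering and 3, among them Rorb (-0.47, adjusted p = 0.106), no longer passed. Fst was then at -2.63, and Enpep at +4.88, Nfix at +1.74 and Meis1 at +2.77. Of 51 G2 and M phase genes 8 were higher and 1 lower, against 1 and 3 of 41 after re-clustering. Of 38 S phase genes 2 were lower, against 20 of 37 after re-clustering, and of 13 mitochondrially encoded genes 9 were higher and 2 lower in both.

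A pair of clusters led by Fgf20 and Tectb, 1 per age, was compared after the data had been seen, because no E12.5 cluster was named prosensory. In it the cell cycle inhibitor gene Cdkn1b, which marks exit from the cell cycle in the sensory domain, rose from 72.6 ± 15.6 to 208 ± 29.5 CPM (n = 2 libraries per age, log2 +1.57, SE 0.21, adjusted p = 4.76e-05). Of 31 S phase genes 27 fell (30 adjusted over the list alone). Of 16 G2 and M phase genes 6 fell (6 adjusted over the list alone). No set test was run here. Each age was clustered on its own, and at E12.5 cycling cells gathered in another epithelial cluster (69 of 105 cells there against 4 of 45 here). The share of cycling cells in the pair differed by -6.20 points, by +0.391 under 5% mitochondrial UMIs and by +1 with at least 2 UMIs. The change is therefore one of the clusters as drawn, and exit from the cell cycle is not shown. Of 13 mitochondrially encoded genes 9 rose and 2 fell (median log2 +0.60). Mcm5 fell from 81.6 ± 7.23 to 14.1 ± 3.30 CPM (-2.57, SE 0.30), and Rrm2 (-2.76, SE 0.40), Gmnn (-2.54, SE 0.26), Lig1 (-2.25, SE 0.26), Hells (-2.18, SE 0.25) and Pcna (-2.0, SE 0.21) fell with it. Sox2 rose from 261 ± 23.8 to 423 ± 24.5 CPM (+0.72, SE 0.14), the Notch effector gene Hey2 from 55.8 ± 11.2 to 159 ± 10.6 CPM (+1.48, SE 0.21) and the FGF feedback genes Spry2 and Dusp6 by +1.67 (SE 0.17) and +1.85 (SE 0.24). Hes1 fell from 684 ± 394 to 35.4 ± 3.73 CPM (-4.25, SE 0.29, adjusted p = 4.99e-08).

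The largest increases in this pair were the G protein subunit gene Gng8 (log2 +4.71, SE 0.50), Cpxm2 (+4.6, SE 0.57), the tachykinin gene Tac1 (+3.86, SE 0.98), Sepp1 (+3.40, SE 0.73), Rprm (+3.34, SE 0.30), Tm4sf1 (+3.22, SE 0.33), Ly6h (+3.21, SE 0.34), Mia (+3.04, SE 0.27), Anxa2 (+3.03, SE 0.41) and Tril (+2.95, SE 0.41). Other decreases were Ccdc85b (-2.69, SE 0.30), the matrix signalling gene Ctgf (-2.63, SE 0.23), Lars2 (-2.23, SE 0.29) and Rgcc (-2.20, SE 0.26). Isl1 (+0.87, SE 0.12), Gata3 (+0.68, SE 0.11), Emx2 (+1.89, SE 0.25), Nr2f2 (+1.58, SE 0.39), Lgr5 (+1.61, SE 0.34), Hmga2 (+0.62, SE 0.15) and Cyp26b1 (+2.20, SE 0.33) rose, and the hair bundle gene Espn fell (-1.82, SE 0.40). Bmp4 had no UMI at E12.5 and was at least 5.87-fold higher at E14.5, taking the group's floor of 3 counts. Jag1 (-0.20, SE 0.12), Fst (+0.68, SE 0.31), Ptch1 (-0.26, SE 0.22) and Gli1 (+0.18, SE 0.43) did not pass. The immediate early genes Fos (+1.72, SE 0.23) and Fosb (+2.13, SE 0.44) rose while Jun fell (-0.78, SE 0.14). Of 7507 genes tested with edgeR and Benjamini-Hochberg adjustment, 405 were higher and 523 lower, and 125 and 216 with DESeq2. The sums held 21, 25, 50 and 97 cells, and Sox2, Cdkn1b, Isl1, Hey2, Lgr5 and Fgf20 were among the markers that named the E14.5 cluster.

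Over all sorted cells, the genes with the largest increases were known from myeloid cells or led clusters outside the otic epithelium. The myeloid genes S100a9, Lyz2 and Tyrobp had no UMI at E12.5 and were at least 1043-fold, 632-fold and 589-fold higher at E14.5, and the forebrain and olfactory gene Fezf1 at least 608-fold, taking the group's floor of 3 counts. S100a8 (log2 +11.67, SE 0.88), Fcer1g (+10.69, SE 0.29), the homeobox gene Pitx1 (+9.48, SE 0.67), the complement gene C1qb (+9.07, SE 0.20), Tesc (+6.24, SE 0.40) and the olfactory G protein gene Gng13 (+5.77, SE 0.26) followed. The smooth muscle genes Acta2 (-4.98, SE 0.84) and Tagln (-3.56, SE 0.39) fell most, then Mab21l2 (-2.90, SE 0.39), Ppp1r17 (-2.67, SE 0.31), Hist1h2ap (-2.59, SE 0.16), the hindbrain gene Hoxb2 (-2.38, SE 0.67), Ccdc85b (-2.37, SE 0.21), Smpd3 (-2.37, SE 0.11), the neuronal Mir124-2hg (-2.35, SE 0.57) and Mreg (-2.31, SE 0.36). Acta2 and Tagln were lead genes of an E12.5 cluster of 7 cells, and Mab21l2, Ppp1r17 and Hoxb2 of neuron-like clusters. For these genes a change in the mix of cells cannot be told apart from a change within cells. Sox2 rose from 75.3 ± 1.19 to 138 ± 25.6 CPM (+0.77, SE 0.12), while the reporter transcript Egfp fell from 237 ± 1.14 to 95 ± 13.6 CPM (-1.42, SE 0.10). Lin28b (-1.52, SE 0.16), Fst (-1.21, SE 0.33), Jag1 (-0.76, SE 0.07), Fgf10 (-0.72, SE 0.16) and Cdkn1b (-0.61, SE 0.07) fell and Fgf20 rose (+0.55, SE 0.14). Of 15851 genes tested with edgeR and Benjamini-Hochberg adjustment, 3190 were higher and 2870 lower. The counts were 942 and 894 without E12.5 replicate 1, 1085 and 1015 without E12.5 replicate 2, and 1083 and 1457 in cells with an Egfp UMI.

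To address the axis from apex to base, epithelial cells other than roof-like cells were scored by the apical genes Fst, Msx1, Hmga2 and Lin28b against the basal genes Inhba and A2m, and in each library the upper and lower ranges, with equal numbers of cells, were compared. In the upper range Tac1 reached 550 CPM against 1.45 CPM in the lower range (log2 +8.87, SE 0.44, adjusted p = 3.81e-06, higher in 4 of 4 libraries), with the gene at 7554879 to 7565834 on chromosome 6. The orphan nuclear receptor gene Nr2f2 stood at 446 and 31.5 CPM (+3.71, SE 0.18), the Wnt antagonist gene Frzb at +5.51 (SE 0.47) and the vessel ligand gene Angpt1 at +4.68 (SE 0.37). The matrix gene Smoc2 (-4.81, SE 0.26) and Aldh1a3, which makes retinoic acid (-4.12, SE 0.26), were lower in the upper range in 4 of 4 libraries. The netrin receptor gene Unc5c (+4.10, SE 0.36), Clu (+3.59, SE 0.42), Lor (+3.59, SE 0.45), Ntng1 (+3.42, SE 0.27), Hs3st1 (+3.22, SE 0.32) and Rprm (+3.18, SE 0.31) were higher. Cryab (-4.11, SE 0.52), Rgcc (-3.48, SE 0.35), Igfbp2 (-2.43, SE 0.41), Padi2 (-2.30, SE 0.31), Tmod1 (-2.25, SE 0.20), Gpc3 (-2.19, SE 0.20), Cenpf (-2.18, SE 0.44) and Hist1h1b (-2.18, SE 0.40) were lower.

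Fixed gene lists were counted between the score ranges, with no set test. Of 51 G2 and M phase genes 44 were lower in the upper range (49 adjusted over the list alone), and of 38 S phase genes 26 were lower (36 adjusted over the list alone). With ranges taken within each cluster 0 of 51 and 0 of 38 were lower, and 1 S phase gene was higher. Examples over the whole ranges were Hmgb2 at log2 -1.62 (SE 0.21), Birc5 at -1.88 (SE 0.28) and Pcna at -1.31 (SE 0.23). Of 17 BMP and activin genes 11 were higher and 1 lower, counts that were the same adjusted over the list alone. With ranges within each cluster they were 3 and 0. Bmp4 (+2.09, SE 0.35), the pseudoreceptor gene Bambi (+1.65, SE 0.17), Id4 (+1.47, SE 0.17) and Id2 (+1.05, SE 0.13) were higher over the whole ranges. Of 14 FGF genes 5 were higher and 1 lower (6 and 1 adjusted over the list alone; 3 and 0 of 13 within clusters), with Fgf20 (+2.02, SE 0.37), the target gene Etv5 (+1.56, SE 0.20) and Spry2 (+1.32, SE 0.19) higher. Of 11 supporting cell and prosensory genes 7 were higher and 1 lower (8 and 1 adjusted over the list alone; 4 and 0 within clusters), including Isl1 (+2.97, SE 0.17), Lgr5 (+2.05, SE 0.22) and Cdkn1b (+1.22, SE 0.14). Of 11 Notch genes 3 were higher (4 and 1 lower adjusted over the list alone; 2 and 1 within clusters), with Hey1 (+1.13, SE 0.11) and Hey2 (+1.51, SE 0.25), and of 15 Wnt genes 4 were higher and 1, Rspo2 (-2.06, SE 0.23), lower (5 and 1 adjusted over the list alone; 1 and 1 within clusters). Of 12 retinoic acid genes 3 were higher and 2 lower (4 and 2 adjusted over the list alone; 1 and 2 within clusters), with the receptor gene Rxrg (+1.75, SE 0.17) and the degrading enzyme gene Cyp26a1 (+3.17, SE 0.67) higher. The Hedgehog target Gli1 was higher at 17.9 against 7.82 CPM (+1.34, SE 0.34, adjusted p = 0.0271) and Ptch1 did not pass over all genes (+0.58, SE 0.21, adjusted p = 0.0998), while both passed adjusted over the list alone. Of 9 Hedgehog pathway genes Gli1 was higher and Boc (-1.23, SE 0.24) lower, in both adjustments, and none of 8 passed within clusters.

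Further lists were counted between the ranges in the same way. The heterochronic genes Igf2bp2 (log2 +1.13, SE 0.14) and Trim71 (+1.60, SE 0.31) were higher among 4 tested (2 adjusted over the list alone; 1 within clusters). Of 20 otic transcription factors 4 were higher, led by Gata3 (+2.06, SE 0.13), and 5 lower, with Irx3 at -1.17 (SE 0.11), against 5 and 5 adjusted over the list alone and 2 and 2 within clusters. Of 13 mitochondrially encoded genes 9 were higher (12 adjusted over the list alone; 1 within clusters), with mt-Co1 at +0.72 (SE 0.08). Cdkn1b and Btg2 (+1.06, SE 0.29), the latter also on the dissociation response list, were higher among 5 cell cycle inhibitor genes. Cdkn1c (-0.77, SE 0.19) was lower. The counts were 3 and 2 adjusted over the list alone, and 0 and 1 within clusters. Of 10 tectorial genes Col9a1 was higher (+0.64, SE 0.11) and Otoa (-5.61, SE 0.45) and Tecta (-1.52, SE 0.26) lower (2 and 3 adjusted over the list alone; 0 and 0 of 9 within clusters). Atp1b2 was higher among 4 ion transport genes (2 and 1 lower adjusted over the list alone; 0 and 0 within clusters) and Espn lower among 4 hair cell genes (2 adjusted over the list alone). Within clusters Espn did not pass (-0.52, adjusted p = 0.346) and 1 other hair cell gene was lower. The dissociation response list had 1 higher and 1 lower of 13 in both adjustments, and 0 and 1 of 14 within clusters. Sox2 did not pass over the whole ranges (+0.54, SE 0.18, adjusted p = 0.0763) but was higher with ranges within each cluster (+0.65, SE 0.10, adjusted p = 9.25e-04).

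Of 8365 genes tested with edgeR with the library as a term and Benjamini-Hochberg adjustment, 482 were higher and 626 lower in the upper range, and 1088 of the 1108 called genes went the same way in 4 of 4 libraries. The ranges were not evenly mixed: lateral-like clusters gave 54.1% to 78.3% of the cells in the upper range, and the E12.5 cluster rich in histone genes or the E14.5 medial-like cluster gave 80.0% to 94.9% of those in the lower range. With ranges taken within each cluster, 110 genes were higher and 69 lower, and 147 of the 1108 remained, including Tac1 (log2 +5.48), Frzb (+2.92), Angpt1 (+2.29), Nr2f2 (+2.31), Isl1 (+1.02), Smoc2 (-2.86), Aldh1a3 (-2.22) and Cryab (-2.22). Smoc2, Aldh1a3, Cryab and Otoa are among the 10 lead genes of an E12.5 vestibular-like cluster, whose cells were not scored. Tac1, Clu and Hs3st1 are among the 10 lead genes of the E12.5 lateral-like cluster, as are the score genes Fst and Hmga2. With ranges within each cluster Bmp4 was at -0.01, Fgf20 at +0.38, Lgr5 at +0.20, Tecta at +0.09, Cenpf at +0.04, Lor at +0.33, Pcna at +0.35 and Birc5 at +0.32, and none of these passed. The counts were 320 and 291 without E12.5 replicate 1, 256 and 241 without E12.5 replicate 2, 220 and 172 without E14.5 replicate 1, 310 and 418 with DESeq2 and 839 and 1083 with no filter. The basal side of the score was thin, since A2m had no UMI in the scored cells and Inhba had 16, 11, 2 and 47 UMIs in the 4 libraries.

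**Figure D3:**
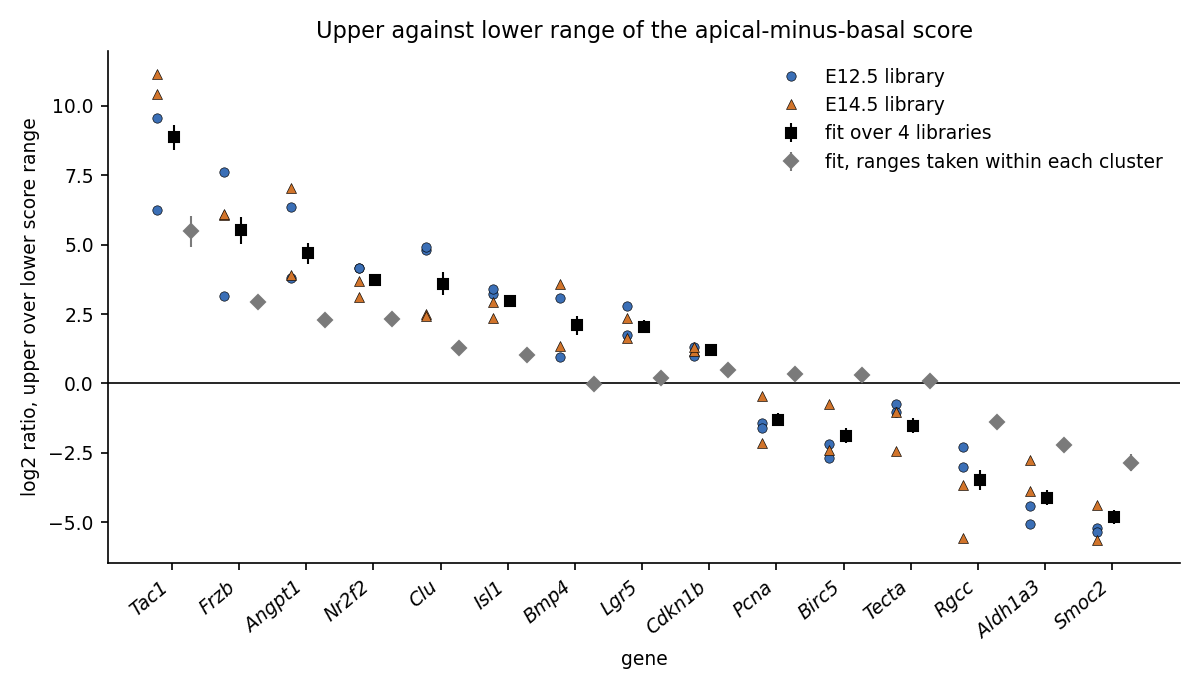
Log2 ratio of the upper over the lower score range for 15 genes, with 1 point per library (blue circles, E12.5; orange triangles, E14.5), the fit over 4 libraries with its SE (black squares) and the fit with ranges taken within each cluster with its SE (grey diamonds). Tac1 lies at +8.87 and +5.48 in the fits, and Bmp4 moves from +2.09 to -0.01.

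The difference between the score ranges changed with age for few genes. Clu, which encodes the secreted chaperone clusterin, was higher in the upper range by a log2 of 4.80 and 4.92 in the E12.5 libraries and 2.52 and 2.42 in the E14.5 libraries, a change of -2.41 (SE 0.15, adjusted p = 1.87e-05). The proteoglycan gene Dcn went from ratios of 3.82 and 1.90 to -1.65 and -1.0 (change -3.91, SE 0.45, adjusted p = 0.00304). The zinc finger gene Sall3 went from -1.89 and -1.85 to 0.29 and 0.78 (change +2.48, SE 0.29), and the actin bundling gene Fscn1 from -1.14 and -1.26 to 0.70 and 1.80 (change +2.65, SE 0.34). Of 9230 genes tested with edgeR and Benjamini-Hochberg adjustment, the difference was higher at E14.5 for 12 and lower for 9. The counts were 26 and 34 without E12.5 replicate 1, 81 and 34 without E12.5 replicate 2, 294 and 224 without E14.5 replicate 1, 44 and 93 without E14.5 replicate 2, and 5 and 6 with DESeq2. With no filter they were 117 and 99, and with ranges within each cluster 2 and 1, with Clu then at +0.06.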

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

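The tests of sequencing depth, of reporter level and of free RNA were chosen only after the result was seen.

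The difference between upper and lower score range changed with age, by a test of the interaction itself, upward for 12 genes and downward for 9. The named ones were Fscn1 (log2 change 2.65), Sall3 (2.48), Pax2 (2.32) and Fundc2 (2.15) upward and Dcn (-3.91), Muc15 (-2.81), Clu (-2.41), Lum (-2.40) and Myl9 (-2.34) downward. Each library moved these counts: they were 26 and 34 without E12.5 replicate 1, 81 and 34 without E12.5 replicate 2, 294 and 224 without E14.5 replicate 1, and 44 and 93 without E14.5 replicate 2. With ranges taken within each cluster 2 passed upward and 1 downward, and of the 9 named genes 8 no longer passed and 1 reversed; the lower range came mostly from the cluster rich in histone genes at E12.5 and from the medial-like cluster at E14.5.

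The E14.5 libraries held UMIs of transgenes that are not part of the labelled genotype: 1505 of Creert2, 370 of TdTomato and 437 of Eyfp, against 11 and 8, 8 and 13, and 7 and 7 in the E12.5 libraries. Of 1056 cells in 9 E14.5 clusters, picked for a Sox2 UMI in at least 60% and an Egfp UMI in under 25% of cells, 89.3% had a Sox2 UMI, 5.30% an Egfp UMI and 54.0% a Creert2 UMI (exact interval 50.9% to 57.0%). Shallow sequencing of these cells was argued against by their depth. Their median was 22315 UMIs, against 14745 in 6 E14.5 clusters with Sox2 and Egfp UMIs in at least 60% of cells each. Of those with over 14745 UMIs 5.13% had an Egfp UMI, a share that the picking of the clusters kept low and that decides nothing alone. Of E12.5 cells with a Sox2 UMI and no more UMIs than that, 88.8% had one. Free RNA spread over all cells was argued against too, since macrophage-like and endothelium-like cells had a Creert2 share of at most 2.78% against 54.0%. Cells of animals with another transgene in the same libraries may account for the pattern: in otic clusters, cells with a Creert2 UMI had an Egfp UMI in 42.9% (3 of 7 cells) against 83.1% in replicate 1 (Fisher's exact p = 0.0222, two-sided) and in 16.3% (8 of 49) against 76.8% in replicate 2 (p = 1.56e-17), with p-values that count cells of 1 library. Low expression of the reporter stays open, because the 9 clusters were picked by Egfp (5.11% of their cells with at least 3 Sox2 UMIs had an Egfp UMI), as does an untested difference of age in the tissues that entered the sort.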

How the results depend on the processing

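The Egfp-only, re-clustered, within-cluster and top-doublet-score alternatives, the 5% mitochondrial limit for cycling cells and all those of the Fgf20 clusters, were chosen only after the result was seen. Of the genes named and called, 52 of 85 in the epithelium, 12 of 27 in all cells, 36 of 65 in lateral-like cells, 4 of 24 in roof-like cells, 48 of 66 in the Fgf20 clusters and 28 of 68 between score ranges kept their direction and their side of the threshold in every alternative run; in the interaction 0 of 9 did, of which 8 were not called in some and 1 reversed. RLE scaling moved the share of called genes that were higher by at most 2.88 points. A simulated 2-fold change was recovered for 66.3% of genes in roof-like cells (sums of 31 to 141 cells), 50% in lateral-like cells and 39.8% in the Fgf20 clusters, against 94% in the epithelium. These rates hold for genes above a minimum level. The age comparisons of prosensory-like and medial-like cells and their interaction were not run, nor was the lower clustering resolution for lateral-like and roof-like cells. Fits without a library leave 1 sample in an age and assume that it varies like the others. The cause of a change was not tested unless given.

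Counts of genes higher and lower were, with DESeq2, 556 and 1010 in the epithelium, 144 and 183 in lateral-like cells, 86 and 175 in roof-like cells, 125 and 216 in the Fgf20 clusters and 310 higher between score ranges, and the interaction had 5 higher. With no filter, under which more genes were tested, they were 652 higher in lateral-like cells, 812 and 848 in roof-like cells, 839 and 1083 between score ranges and 117 and 99 in the interaction. In cells with an Egfp UMI, which are fewer, they were 1221 lower in the epithelium, 1083 and 1457 in all cells, 295 lower in lateral-like cells and 187 and 286 in roof-like cells. Re-clustering gave 729 and 909 and the replicate number as a term 583 and 720 in roof-like cells. Without the library as a term 301 and 347 genes differed between score ranges, and with ranges within each cluster 110 and 69, with 2 and 1 in the interaction.

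Leaving out 1 library at a time gave 374 to 1925 genes higher and 648 to 2173 lower in the epithelium, 942 to 3071 and 894 to 2681 in all cells, 188 to 739 and 193 to 726 in lateral-like cells, 4 to 879 and 13 to 953 in roof-like cells, 331 to 497 and 402 to 494 in the Fgf20 clusters, 220 to 636 and 172 to 827 between score ranges, and 26 to 294 and 34 to 224 in the interaction. In the epithelium and in all cells the low values came without an E12.5 replicate (578 and 871 or 374 and 648; 942 and 894 or 1085 and 1015). Camera called 4 lists higher and 2 lower, 0 and 0 with an estimated correlation (smallest adjusted p = 0.406; fry called 4 of the 6), and 2 to 6 lower when 1 library was left out, with 6 without E14.5 replicate 1 and 6 without E14.5 replicate 2. The median log2 of the G2 and M phase list was 0.20 in all sorted cells and 0.00288 after re-clustering.

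The epithelial share differed by -16.6 points at Leiden resolution 0.6, where an E12.5 vestibular-like cluster was named otic and E14.5 roof-like cells joined a vestibular-like cluster, and by 3.04 in cells with an Egfp UMI. The lateral-like share then differed by 4.05 (resolution 0.6), since no E12.5 cluster was named lateral and its cells became otic epithelium, and the vestibular-like by -1.38; the roof-like differed by 0.601, the unnamed by -2.70 and the glia-like by 20.1 (Egfp only). Under 5% mitochondrial UMIs the prosensory-like share differed by 1.33 and the lateral-like by -4.48. The cycling share of the Fgf20 clusters differed by 1 point with at least 2 UMIs, by -14.7 without thinning and by 0.391 under 5% mitochondrial UMIs, where that of the epithelium differed by 8.82.

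Log2 changes that reversed in the epithelium at resolution 0.6 were Pthlh -1.30, Cdkn1b 0.38, Notch2 -0.070, Fgfr2 -0.60, Cib2 -0.032, Myo6 -1.29 and Meis1 -0.77; there the E12.5 epithelium took in a vestibular-like cluster and the E14.5 epithelium lost its roof-like cells, and no fit separates these. After re-clustering Pthlh was -0.22 in the epithelium, Oc90 -0.71 in lateral-like and Aldh1a3 -1.13 in roof-like cells. Over the fits with 1 library left out, Hmga2 ran from -0.34 (without E14.5 replicate 1) to 0.69 in the epithelium and from -0.56 to 0.28 (without E14.5 replicate 2) in lateral-like cells, and Atoh1 from -2.10 to 0.64 (without E14.5 replicate 1) in all cells. In all cells with an Egfp UMI Fgf10 was 0.00426 and Bmp4 0.39. With score ranges within each cluster Cenpf was 0.042, Hist1h1b 0.28, Prim1 0.41, Tyms 0.058, Nasp 0.017, Pcna 0.35, Hmgb2 0.24, Birc5 0.32, Cdca8 0.21, Col9a1 -0.076, Tecta 0.087 and Bmp4 -0.015, and Clu 0.057 in the interaction. With a score without Hmga2 and Lin28b Fgf20 was -0.59, Sox2 -0.41, Fgf10 -1.64 and Jag1 -0.65.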

Other observations

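The choice of Shh and of the clusters described here, and all tests of this part except that of X-linked and Y-linked genes, were made only after the result was seen.

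Shh, the ligand of the Hedgehog pathway, was found in neuron clusters with Gata3 and Isl1, a pair of genes that spiral ganglion neurons express. These held 0.381 and 0.405 Shh UMIs per 10000 at E12.5 and 0.832 and 0.553 at E14.5, in 82, 112, 121 and 88 cells. The cochlear epithelium held 0, 1, 0 and 1 Shh UMIs in 150, 174, 184 and 614 cells, so the neurons were at least 41.4-fold higher in E12.5 replicate 1 and at least 118-fold higher in E14.5 replicate 1, taking a floor of 3 counts per library. The share of these neurons with an Shh UMI was 45.1%, 42.0%, 52.1% and 50%.

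Several E14.5 clusters were led by genes of tissues other than the ear. A cluster of 251 cells was led by the detoxifying enzyme genes Cyp2g1, Gstm1 and Sult1e1, which olfactory sustentacular cells express, and a cluster of 306 cells by Rtp2, Gfy and Gng13, genes of olfactory neurons. A cluster of 225 cells, all from E14.5 replicate 2, was led by the pituitary genes Cga, Pomc and Pou1f1. A cluster of 194 cells was led by Neurod6, Bhlhe22 and Fezf2, genes of cortical neurons. Clusters led by the choroid plexus gene Ttr had 12 cells at E12.5 and 70 at E14.5. An Egfp UMI was present in 1.20%, 2.29%, 1.78% and 2.06% of the cells of the first 4, against 90.5% in the prosensory-like cluster.

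The upper and lower score ranges differed in 1108 genes, and the mix of clusters in the ranges may account for most of this, since 98.3% of these genes had the sign of the difference between lateral-like and other clusters (83.1% of tested genes did) and 179 genes passed with ranges taken within each cluster. A score of other genes with like expression could do as much: 2 of 20 random scores called at least as many genes (median 289.5, highest 1543), and with ranges within each cluster 4 of 20 reached 179 (median 45.5, highest 325). The 8 splits that swap upper and lower sums within libraries are too few for a share under 0.05; the real one called 1108 genes and the highest of the others 0. Position along the duct was not measured, and it stays open as a source of the genes that passed within clusters, such as Tac1 and Nr2f2, as do vestibular-like cells left in the scored clusters for Smoc2, Aldh1a3 and Cryab. Tac1 is a lead gene of the E12.5 lateral-like cluster, as are the score genes Fst and Hmga2. How far lateral-like cells left in other scored clusters account for Tac1 was not tested.

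Xist and Y-linked genes separated the ages. X-linked and Y-linked genes were 3.11% of the genes called in the epithelium (exact interval 2.54% to 3.76%) and 3.44% of those tested, so they were not over-represented among the calls. Of 11602 tested genes with a known chromosome, 399 were X-linked or Y-linked and 3281 were called. So few could not have been the main source of the calls in any case, and their share does not bear on sex effects through autosomal genes. A pool of both sexes in any library is argued against, because the rarer of the 2 kinds of cell made up at most 0.733% of a library. An effect of sex on autosomal genes could still add to any age difference in these libraries, because sex and age coincide.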
